A study of Mus musculus with 22 samples.

How the data were processed

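Gene expression was measured in epididymal white adipose tissue, the abdominal fat pad attached to the epididymis, of male C57BL/6JOlaHsd mice, an inbred laboratory strain. Per the labels' protocols, the mice were fed a purified diet with 10% of energy from fat for 3 weeks and then a diet with 40% of energy from fat for 6 weeks. They were then fasted and kept for 6 hours at 20.9% oxygen (normoxia, 12 mice) or at 12% oxygen (hypoxia, 10 mice) in a calorimetry system. The treatment protocol also mentions low-fat feeding beside high-fat feeding without naming mice, so diet was not modelled. Total RNA of each mouse was labelled with Cy5 and hybridised to a 2-colour Agilent array against a Cy3-labelled pool of all samples, with no dye swap. The series text describes the samples of a group as biological replicates.

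The deposited scanner files were written by Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The mean signals and local median backgrounds used here are deposited intensity values as scanned, without normalization. The log10 ratio of Cy5 over Cy3 in the same deposited files carries Feature Extraction's own background subtraction and dye normalization, per the file headers. The deposited value table of the series holds log2 values for 33845 spots. In it every array has a median of 6.299, and its columns correlated with the log2 Cy5 signal of their arrays at 0.902 to 0.999. The correlation with Cy3 was lower than that with Cy5 except on normoxia replicate 6 (0.962 against 0.902), hypoxia replicate 3 (0.978 against 0.971) and normoxia replicate 2 (0.972 for each channel). The table therefore holds levels with equal medians and not ratios, for most arrays closer to Cy5, and how the authors normalized it is not given in the sources used here. Its rows were matched to spots by feature number.

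Each array holds 62976 spots, of which 59305 are biological, with 55681 probes. The arrays lie on 6 slides. Slides 1, 3, 4, 5 and 6 carry 2 normoxia and 2 hypoxia arrays each, and slide 2 carries normoxia replicates 9 and 10 alone. All slides were scanned on 1 day at 1 time each, so that scan date is no batch apart from the slide. The share of spots well above background in Cy5 ran from 15.6% (hypoxia replicate 7) to 76.8% (hypoxia replicate 3). It was below 19% on the 4 arrays of slide 1 (normoxia replicates 3 and 5, hypoxia replicates 5 and 7). In Cy3 the share was over 80% on 3 arrays (normoxia replicates 2 and 6, hypoxia replicate 3). The number of arrays limits the precision: the median standard error of a gene's log2 difference was 0.098.

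The background was corrected with normexp and an offset of 50, and each array was normalized by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots with a non-uniformity or population outlier flag in either channel were left out, and saturated spots were kept. No scaling between arrays was applied. Spots of a probe were averaged. A probe was tested where Cy5 was well above background on at least 10 arrays and at least 2 unflagged values per group remained. A gene with several probes was represented by the probe with the highest mean log2 intensity. Of the 3728 genes with more than 1 tested probe, 1714 had probes with differences of both signs. Gene names came from the files and were updated through the RefSeq table of assembly GRCm38.p6, which was used for names and to compare the chromosome of 1 probe. In this way 27235 probes were named by accession, 3581 by symbol and 565 by a synonym of a single gene, and 24300 kept the name in the file. Probe coordinates are those of the files, on mm9. No genome sequence of that build was used here, so that the exon or UTR under a probe is not given.

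The log2 ratio to the pool was fitted with group as the only term (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The difference is always hypoxia minus normoxia. The 42 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 41 lists with at least 5 measured members. The list of epididymis markers had 4 measured members and was not tested. Camera was repeated with an estimated correlation, and fry tested whether a list moves one way. A list score per mouse is the mean over the measured members of the log2 ratio less its mean over all arrays. Group differences of scores were tested by a two-sided permutation test with 100000 resamples, adjusted over the lists, and again with labels permuted within the 5 slides that carry both groups. Lists share members, so their tests are not independent. Adjusted p-values of lists are camera's at the preset correlation unless another test is named.

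Lists, tests, alternatives and the rule for named genes were set before the data were examined, except where stated. By that rule, the text can name genes past the threshold, the 10 genes with a symbol and the smallest unadjusted p where fewer than 10 pass, up to 4 passing members of each list or its 2 members of smallest p where none passes, and 18 genes fixed in advance. The rule gave 95 tested genes. The probes of Pip5k1a and Pgk1 were checked after the results were seen.

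The fit was tested on simulated data made from the residuals of the 16578 tested genes with shuffled arrays, in which 200 genes were changed in 10 runs. It recovered 10.4% of genes changed by 0.25 on the log2 scale, 78.5% of those changed by 0.5 and 97.9% of those changed by 1, with 3.3 false calls per run. These rates hold where 200 genes and 10 lists change at once, which eases the p that the adjustment requires. They do not give the rate where few genes change, and in the real data Mt2 did not pass at 1.13. All 10 lists of 25 genes shifted by 0.15 were found, and none of 30 unshifted lists was called. These lists were drawn at random from the genes, while members of real lists can vary together (estimated correlation 0.632 for red blood cell markers). The simulation therefore does not give the rate of false calls for the real lists. In other random splits of the arrays, a median of 4 real lists passed at the preset correlation.

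The alternatives covered no background correction, Feature Extraction's ratio, median centring, Aquantile normalization between arrays, the Cy5 channel alone, the deposited value table, other filters on dim probes, flagged spots kept, other rules for several probes, the slide as a fixed or random block, leaving out slide 2, the replicate number as a block, a trended robust variance, array weights, other set tests and leaving out each mouse. The numbers of the mice do not pair them: correlations of same-numbered deviations from the group means ran from -0.470 to 0.254. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.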

Results

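The study asked how white adipose tissue responds to a short fall in ambient oxygen. Transcripts of epididymal fat were measured in 12 mice kept at 20.9% oxygen and 10 mice kept at 12% oxygen for 6 hours, each as a log2 ratio to a pool of all samples. Of the 16578 genes tested, 12575 carried a gene symbol. The median Cy5 signal per array lay between 35.1 and 108.1 intensity units over median backgrounds of 29.0 to 33.0, and on the 4 arrays of slide 1 fewer than 19% of spots were well above background in Cy5.

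Targets of the hypoxia-inducible factors (HIF) rose as a list in hypoxia, by a mean of 0.13 on the log2 scale (median 0.08) over 39 measured members. The list score was -0.06 ± 0.05 in normoxia (SD, n = 12) and 0.07 ± 0.03 in hypoxia (SD, n = 10). The lowest hypoxia mouse (0.02) lay above the highest normoxia mouse (-0.002). Camera gave an adjusted p of 1.58e-05, and 0.00285 with an estimated correlation. The permutation test of the scores gave p = 1e-05, the smallest that 100000 resamples can give (adjusted p = 0.00041). Of the members, 28 lay above 0 and 11 below. No member passed over all genes tested, and 6 did when adjusted over the list alone, all higher. Among these were the lactate exporter Slc16a3 (0.45 ± 0.13, SE), the lipid droplet protein Hilpda (0.43 ± 0.13) and the glycolytic kinase Pgk1 (0.27 ± 0.08). The files place the Pgk1 probe on chromosome 3, while RefSeq has the gene on chromosome X, so that this value may come from another copy. The score difference was 0.13 averaged within slides, where it ran from 0.08 to 0.18 over the 5 slides with both groups. Permuting within slides gave p = 0.00026, the smallest this design allows, and an adjusted p of 0.0107.

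Glucocorticoid-responsive genes, which stress hormones of the adrenal cortex induce in many tissues, rose as a list by a mean of 0.26 (median 0.24) over 35 members. The score was -0.12 ± 0.11 in normoxia (SD, n = 12) and 0.14 ± 0.18 in hypoxia (SD, n = 10), and all 10 hypoxia mice lay above the normoxia mean. Camera gave an adjusted p of 1.19e-15, and 0.00285 with an estimated correlation. The permutation test gave an adjusted p of 0.00266. Of the members, 32 lay above 0 and 3 below, and 13 passed when adjusted over the list alone, all higher, against 0 over all genes tested. They included the metallothioneins Mt2 (1.13 ± 0.25, SE) and Mt1 (0.75 ± 0.24), which bind zinc and copper, the stress gene Gadd45g (0.72 ± 0.15), the receptor chaperone Fkbp5 (0.46 ± 0.16), the pyruvate dehydrogenase kinase Pdk4 (0.45 ± 0.18), the receptor kinase Mertk (0.31 ± 0.09) and the transcription factor Foxo1 (0.25 ± 0.08). Within slides the mean difference was 0.24, with a range of 0.16 to 0.30 and an adjusted permutation p of 0.013. Hypoxia replicate 7 scored highest at 0.60, and without that mouse the difference was 0.21. Without Mt1 and Mt2 the mean was 0.22 and the list still passed (adjusted p = 3.58e-13, and 0.00316 with an estimated correlation).

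Immediate early genes, which respond to signals within minutes, rose by a mean of 0.17 (median 0.16) over 20 members (adjusted p = 6.15e-06, and 0.011 with an estimated correlation). Above 0 lay 18 members, the number past the threshold over all genes tested was 0, and adjusted over the list alone 1 passed, Fosl2 (0.31 ± 0.08, SE). Ccn1 differed by 0.52 ± 0.18 and did not pass. The permutation test of the score gave an adjusted p of 0.019, and within slides, where the mean difference was 0.16 and the range 0.08 to 0.21, an adjusted p of 0.08. Antioxidant genes and targets of the transcription factor NRF2 were higher by a mean of 0.12 (median 0.08) over 28 members (adjusted p = 0.00406, and 0.027 with an estimated correlation). The list passed only with the metallothioneins. Without Mt1 and Mt2 the other 26 had a mean of 0.06 and a median of 0.07, with 20 above 0. They did not pass as a list (adjusted p = 0.0712, adjusted p = 0.104 with an estimated correlation, and adjusted p = 0.123 for the permutation of scores). Adjusted over the list alone, 1 member passed, Mt2, which is also in the glucocorticoid list, and 22 of 28 members lay above 0. With all 28 members the score difference was 0.11 within slides (range 0.07 to 0.16, adjusted permutation p = 0.013). Hypoxia replicate 7 scored 0.30 and the other hypoxia mice at most 0.12, and in the deposited value table this list did not pass (adjusted p = 0.201). Inflammatory cytokines and acute phase genes rose by a mean of 0.15 (median 0.13) over 20 members (adjusted p = 0.00149, and 0.0404 with an estimated correlation). Of the members, 19 lay above 0 and 1 below, and Vcam1, an adhesion molecule, differed by 0.20 ± 0.11 (SE). The permutation test of this score gave an adjusted p of 0.123, and the difference within slides ran from -0.06 to 0.29 with a mean of 0.15.

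**Figure D1:**
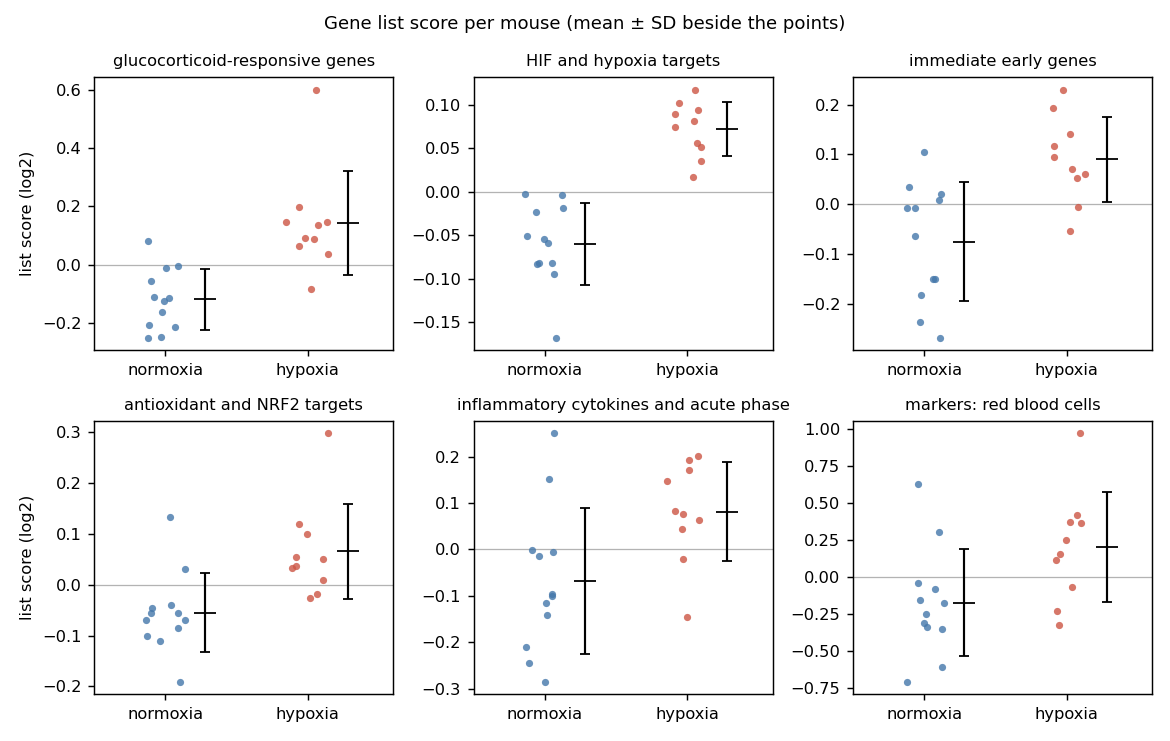
Gene list scores per mouse on the log2 scale for 6 lists, with 12 normoxia points and 10 hypoxia points per panel and mean ± SD beside them. For HIF targets the 10 hypoxia mice lie between 0.02 and 0.12 and the 12 normoxia mice between -0.17 and -0.002, while red blood cell scores overlap.

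Lists of matrix genes and of 3 cell types were also higher in hypoxia, but lost the call with an estimated correlation. Extracellular matrix genes were higher by a mean of 0.12 (median 0.12) over 32 members (adjusted p = 0.000121, and adjusted p = 0.104 with an estimated correlation). Ccn2, a matricellular growth factor, differed by 0.60 ± 0.18 (SE) and the collagen gene Col18a1 by 0.21 ± 0.08, but the other tested Col18a1 probe differed by -0.06. Smooth muscle and pericyte markers were higher by a mean of 0.22 (median 0.20) over 11 members (adjusted p = 0.00198, and adjusted p = 0.0816 with an estimated correlation). Adjusted over the list alone, 2 passed: the contractile genes Tagln (0.48 ± 0.16) and Acta2 (0.34 ± 0.12). Mesothelial markers, of the cells that line the fat pad, were higher by a mean of 0.17 (median 0.16) over 12 members (adjusted p = 0.0118, and adjusted p = 0.531 with an estimated correlation), with Gpm6a at 0.36 ± 0.16 and Upk3b at 0.32 ± 0.17. Without hypoxia replicate 9 the mesothelial mean was 0.07. Red blood cell transcripts were higher by a mean of 0.37 (median 0.36) over 7 members (adjusted p = 6.15e-06, and adjusted p = 0.142 with an estimated correlation). Adjusted over the list alone, 1 passed, the alpha globin Hba-a1 (0.60 ± 0.17), and the beta globin Hbb-b2 differed by 0.43 ± 0.17. Globin genes are near-identical copies whose probes can bind each other's transcripts, so that these values are uncertain between copies. Within slides, the mean differences were 0.15 for matrix (0.01 to 0.27), 0.18 for smooth muscle (-0.16 to 0.41), 0.12 for mesothelium (-0.13 to 0.33) and 0.37 for red blood cells (-0.05 to 1.18). No member of the matrix and mesothelial lists passed over the list alone.

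Together, 9 of the 41 lists tested passed with the preset correlation, all higher in hypoxia, and 5 passed with an estimated correlation. Without Mt1 and Mt2, 8 passed with the preset correlation. Fry called 4 lists, as did the permutation test of the scores. In 100 splits of the arrays, the real one included, 14 gave at least 9 lists with the preset correlation, and the real split alone gave 5 with an estimated correlation. With splits balanced over the slides these numbers were 14 and 1 of 100.

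No single gene passed the threshold in limma's test. The smallest adjusted p was 0.0704, and 879 genes had an unadjusted p under 0.05, 430 higher and 449 lower in hypoxia, where chance alone would give 829. The differences of all genes ran from -0.78 to 1.13 on the log2 scale. The gene with the smallest p was Adgrf5, an adhesion G protein-coupled receptor, at 1.44-fold (log2 0.52 ± 0.09, SE). Its ratio to the pool was -0.14 ± 0.22 in normoxia (SD, n = 12) and 0.38 ± 0.19 in hypoxia (SD, n = 10). With slide as a fixed block Adgrf5 (0.52, adjusted p = 0.0485) and Pip5k1a (1.04, adjusted p = 0.0485) passed, while 0 genes passed with slide as a random block or without slide 2. The probe named Pip5k1a, a lipid kinase gene, differed by 2.03-fold (1.02 ± 0.20, adjusted p = 0.104), but may not measure that gene. It followed Mt2 from mouse to mouse within groups (correlation 0.96) and Mt1 (0.91), the other tested Pip5k1a probe differed by 0.13, and 1 reading frame of its 60 bases holds 5 cysteines in 19 codons, the sequence type of metallothioneins. Mt2 differed by 2.19-fold (adjusted p = 0.193), with hypoxia replicate 7 at 3.02 and the other hypoxia mice between -0.36 and 1.04.

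The others of the 9 genes with a symbol and the smallest p did not pass either. Transcripts without a symbol were left out of this ranking. Depp1, a target of FoxO transcription factors, differed by 1.73-fold (0.79 ± 0.16, SE) and Ccn5, a matricellular protein, by 1.89-fold (0.92 ± 0.21). Gadd45g differed by 1.65-fold. Smad7, an inhibitor of TGF-beta signalling, differed by 1.40-fold (0.49 ± 0.11) and Pla2g7, which degrades platelet-activating factor, by 1.31-fold (0.39 ± 0.08). The other tested Pla2g7 probe differed by 0.14. Syne2, a protein of the nuclear envelope, was the only 1 of the 9 with a lower mean in hypoxia, at 1.48-fold (-0.57 ± 0.11, adjusted p = 0.122), and its other tested probe differed by -0.05. In each of the 9 genes, all 10 hypoxia mice lay on the same side of the normoxia mean, and the difference had the same sign in all 5 slides with both groups. The genes were picked by their p in these same mice, so this agreement is no independent support. On mm9 the probes lay at 43596447 to 43596506 on chromosome 17 for Adgrf5, at 94901128 to 94901187 on chromosome 3 for Pip5k1a, at 116602564 to 116602623 on chromosome 6 for Depp1 and at 96697371 to 96697430 on chromosome 8 for Mt2.

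**Figure D2:**
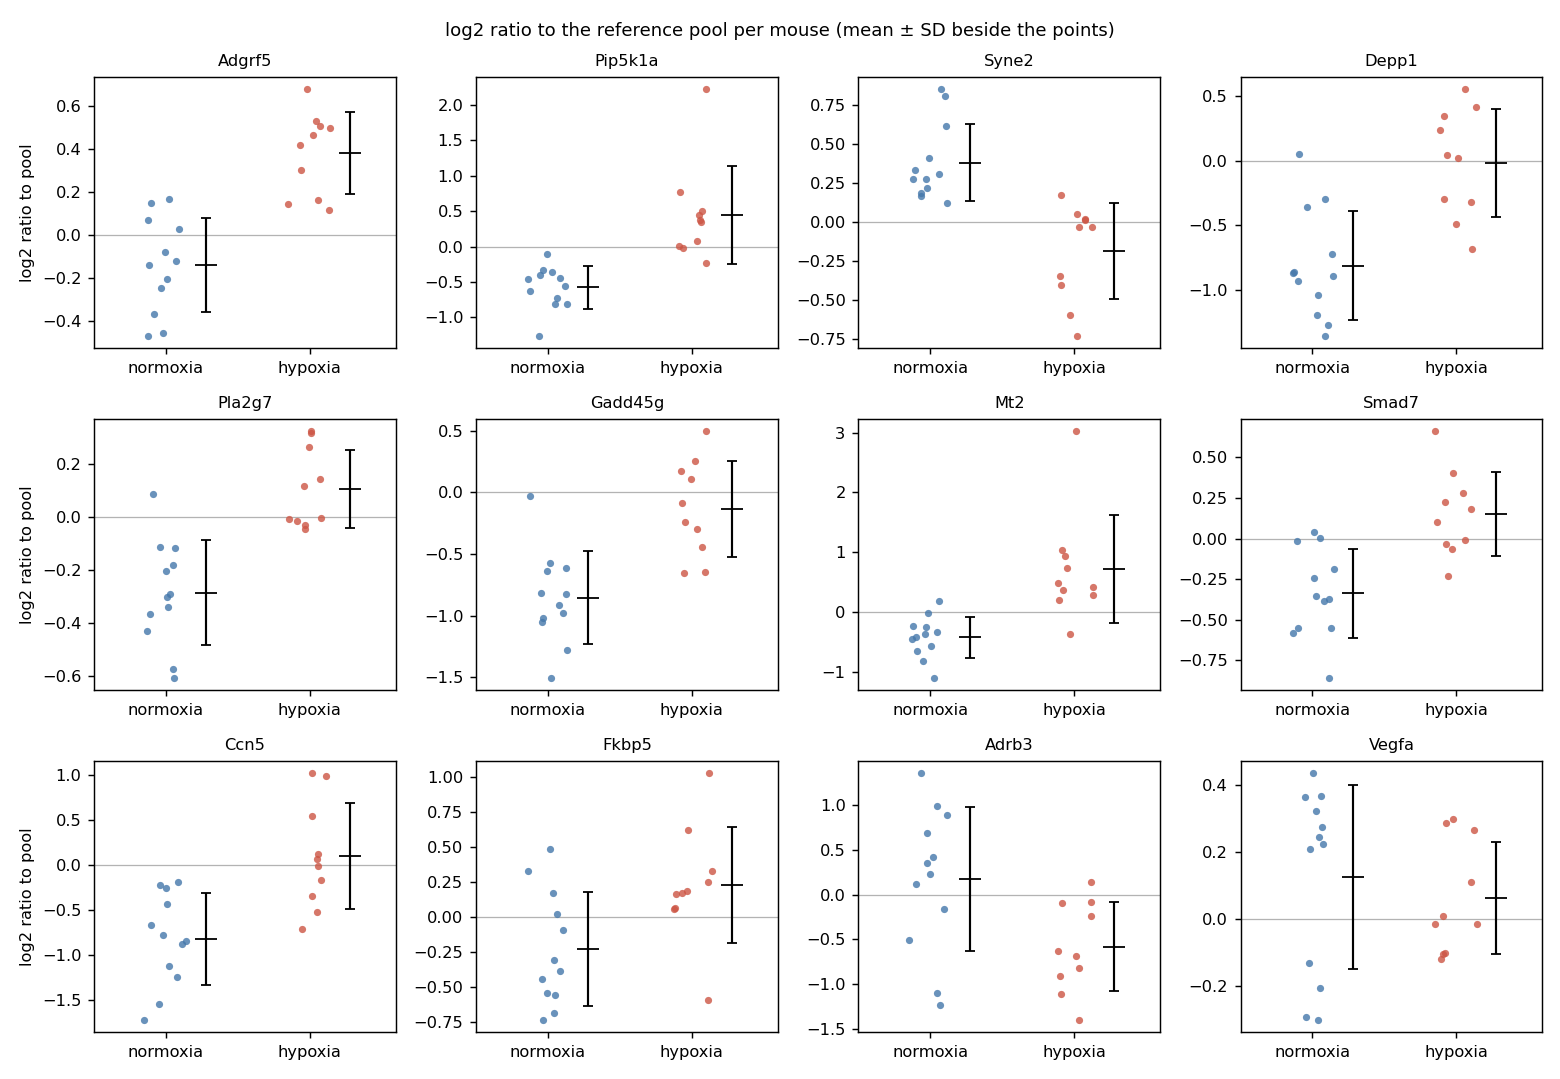
log2 ratio to the reference pool per mouse for the 9 genes with a symbol and the smallest p, and for Fkbp5, Adrb3 and Vegfa. Each panel has 12 normoxia and 10 hypoxia points with mean ± SD beside them. Hypoxia means lie above normoxia means except for Syne2 (-0.57), Adrb3 (-0.76) and Vegfa (-0.06), and hypoxia replicate 7 stands apart in Mt2 at 3.02 and Pip5k1a at 2.21.

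Genes fixed in advance are given here as values, since none passed. Vegfa, the vascular growth factor and a known HIF target, differed by -0.06 ± 0.10 (SE), Hif1a by 0.10 ± 0.10, the glucose transporter Slc2a1 by 0.18 ± 0.15, Pdk1 by 0.19 ± 0.10 and Ldha by 0.07 ± 0.12. The adipokines leptin (Lep) and adiponectin (Adipoq) differed by 0.29 ± 0.18 and 0.17 ± 0.19. The lipases Pnpla2 and Lipe differed by 0.08 ± 0.17 and 0.01 ± 0.13, Fasn by -0.09 ± 0.11, Pck1 by 0.05 ± 0.25, Pparg by -0.04 ± 0.10, Ppargc1a by -0.04 ± 0.15 and Ccl2 by 0.07 ± 0.14. Ucp1 was well above background on at most 3 arrays and Il6 on 0, and neither was tested.

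Lists of metabolic genes did not pass. Among glycolytic genes the median difference was 0.06 over 23 members (adjusted p = 0.0745). Adjusted over the list alone, 2 passed, Pgk1 and Slc16a3, which are also HIF targets. Lipolysis and lipid droplet genes had a median of -0.01 over 28 members (adjusted p = 0.375), and Adrb3, the adipocyte beta-adrenergic receptor, differed by -0.76 ± 0.26 (SE), with all 10 hypoxia mice below the normoxia mean. Thermogenic adipocyte genes had a median of -0.07 over 12 (adjusted p = 0.318), fatty acid synthesis genes -0.05 over 22 (0.594, with Mlxipl at -0.27 ± 0.09), and genes of glyceroneogenesis and triglyceride synthesis -0.07 over 19 (0.399, with Gpam at -0.28 ± 0.12). For fatty acid oxidation and ketone bodies the median was 0.01 over 34 (adjusted p = 0.886), for oxidative phosphorylation -0.01 over 54 (0.399), for the tricarboxylic acid cycle -0.004 over 27 (0.886), and for mitochondrial biogenesis and dynamics -0.04 over 30 (0.399, with the nuclear receptor Esrra at -0.26 ± 0.08). Branched-chain amino acid catabolism had -0.01 over 27 (adjusted p = 0.886), cholesterol synthesis -0.02 over 21 (0.399), insulin signalling -0.04 over 24 (0.399), and adipocyte identity and adipokines 0.02 over 26 (0.752).

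Other regulatory lists did not pass either. Angiogenic factors had a median of 0.05 over 25 members (adjusted p = 0.0745), and 1 passed over the list alone, the VEGF receptor Kdr (0.23 ± 0.07, SE), whose other tested probe differed by -0.17. Medians were 0.02 over 18 for heat shock genes (adjusted p = 0.399), 0.01 over 21 for the unfolded protein response (0.966), 0.01 over 30 for the integrated stress response (0.441), -0.004 over 25 for interferon-stimulated genes (0.594), 0.03 over 19 for the circadian clock (0.436), 0.04 over 20 for the cell cycle (0.399) and 0.06 over 43 for ribosomal proteins (0.203). Of the metabolic and regulatory lists named here, those not mentioned with a member past the list alone had 0.

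Markers of the remaining cell types did not pass in the fit without slides. The medians were 0.09 over 20 for macrophages (adjusted p = 0.0644), 0.15 over 7 for mast cells (0.0676), 0.09 over 9 for neurons and Schwann cells (0.091), 0.11 over 6 for lymph node and its stroma (0.157), 0.03 over 18 for endothelial cells (0.259), 0.06 over 16 for adipose stem and progenitor cells (0.318), 0.12 over 8 for B cells (0.396), 0.03 over 6 for neutrophils (0.816) and 0.01 over 5 for skeletal muscle (0.886). For T and NK cells the median was -0.06 over 12 while the mean was 0.01 and camera's direction was up (adjusted p = 0.886). Testis germ cell transcripts had a median of -0.41 over 5 (adjusted p = 0.338), and their score difference of -0.37 was -0.14 without normoxia replicate 1. With slide as a fixed block 3 of these lists passed: macrophages (median 0.13, adjusted p = 0.00165), stem and progenitor cells (0.11, 0.0255) and testis germ cells (-0.77, 0.0388). Their scores permuted within slides gave adjusted p of 0.147, 0.258 and 0.464. Adjusted over the list alone, 1 member passed in the endothelial list, Kdr again, and 1 in the lymph node list, the chemokine Ccl19 (0.42 ± 0.15, SE).

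**Figure D3:**
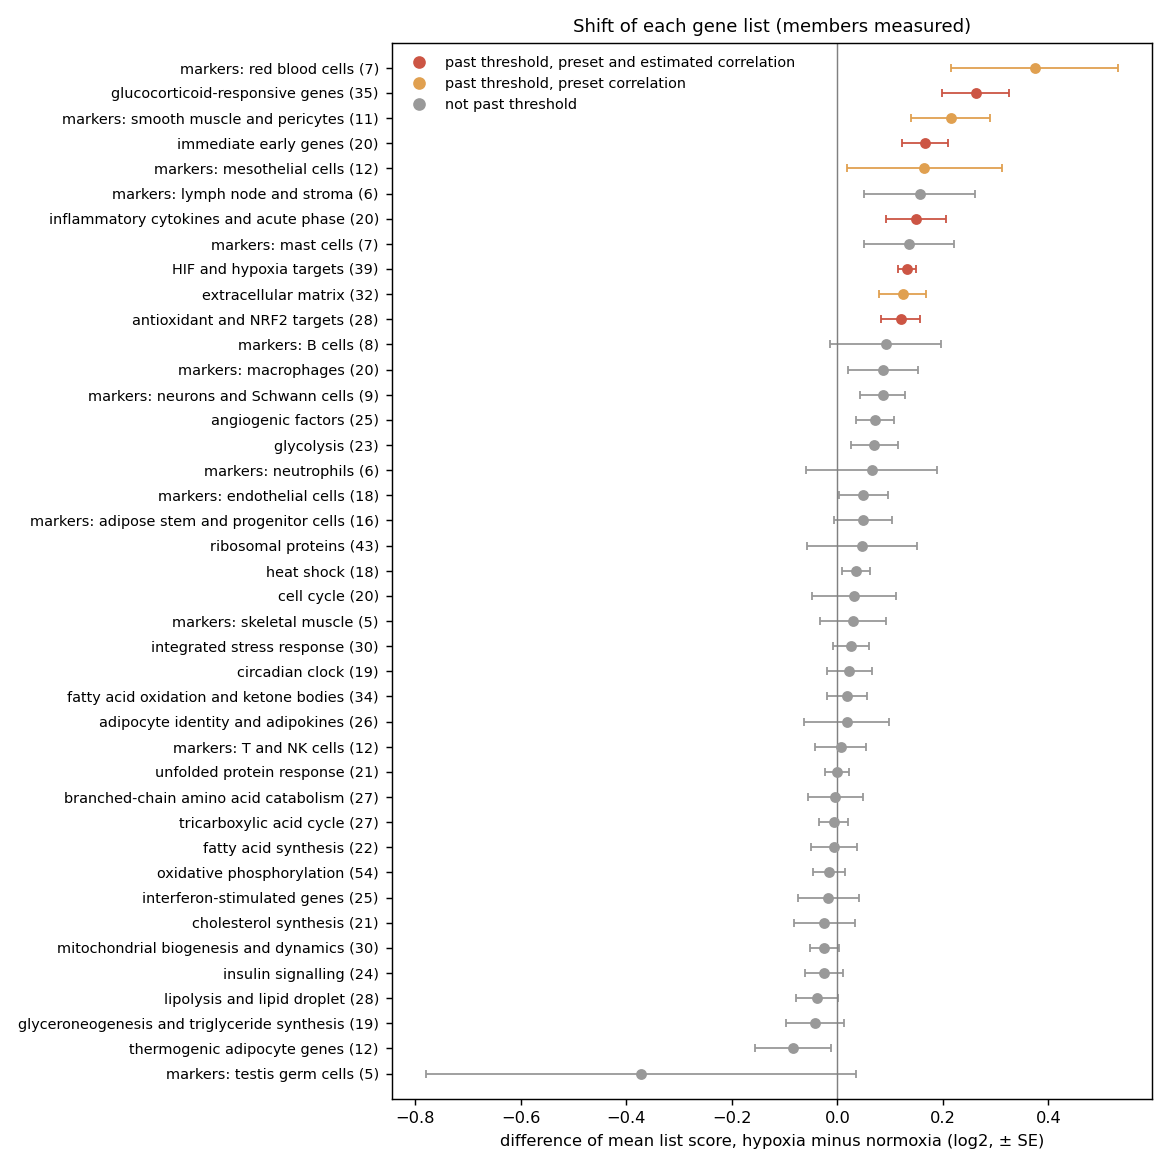
Difference of the mean list score, hypoxia minus normoxia, on the log2 scale with SE (12 normoxia and 10 hypoxia mice), for the 41 lists, with the number of measured members in brackets. Colours mark the 5 lists past the threshold with the preset and an estimated correlation, the others of the 9 past it with the preset correlation, and the 32 not past it.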

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

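Values of the 10 hypoxia mice were searched for a mouse far from the others, over the named genes and the list scores. Of 136 values tested, 13 had one, where chance flags about 1 in 20 groups (6.8 here). The values overlap, since the glucocorticoid and antioxidant scores contain Mt1 and Mt2 and the ribosomal score contains Rpl19. The 13 are therefore not separate events, and whether they exceed chance cannot be read from these numbers. The normoxia group is too large for this rule and was not searched.

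Hypoxia replicate 7, which also had the lowest share of spots well above background in Cy5 (15.6%), stood apart in 7 of them. Its log2 ratio was 2.21 for Pip5k1a (others -0.23 to 0.77, from a probe that follows Mt2), 3.02 for Mt2 (others -0.36 to 1.04), 2.90 for Mt1 (others 0.13 to 0.90) and 0.74 for the ribosomal protein Rpl19 (others -0.29 to 0.20). Its score was 0.60 for glucocorticoid-responsive genes (others -0.08 to 0.20), 0.30 for antioxidant genes (others -0.03 to 0.12) and 0.64 for ribosomal proteins (others -0.17 to 0.25). Without this mouse Adgrf5, Mt2 and Pip5k1a passed the threshold.

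Hypoxia replicate 10 stood apart in Pdk4 at -1.42 (others -0.61 to 0.30) and in the sperm gene Smcp at 1.13 (others -2.35 to -0.58). Hypoxia replicate 6 stood apart in Rps19 at -0.76 (others -0.29 to 0.11) and in S100a9, a neutrophil gene, at 2.20 (others -0.71 to 0.04). Hypoxia replicate 5 had a score of 0.24 for glyceroneogenesis and triglyceride synthesis (others -0.17 to 0.03), and hypoxia replicate 2 a score of 0.41 for macrophage markers (others -0.14 to 0.13).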

How the results depend on the processing

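The count of genes past the threshold, 0 in the reported fit, was also 0 in 30 of its 41 alternatives. It was 1 with Feature Extraction's ratio (Mt2), 2 with the Cy5 channel alone (Mt2, Pip5k1a), 1 with probes well above background on all 22 arrays (Adgrf5, with 6458 genes tested), 2 with slide as a fixed block (Adgrf5, Pip5k1a), 1 with a trended robust variance (Adgrf5) and 4 with array weights (Adgrf5, Gadd45g, Pip5k1a and a clone without a symbol). Leaving out each mouse in turn gave 0 to 3: 1 without normoxia replicate 4, 1 without normoxia replicate 8 and 1 without hypoxia replicate 4, each Adgrf5, and 3 without hypoxia replicate 7. Without the 4 arrays of slide 1, a choice made after seeing the data, it was 2 (Mt2, Pip5k1a), and without the 3 arrays with strong Cy3, also chosen then, 0. The cause was not tested. Genes at an unadjusted p under 0.05 numbered 879, but 72 with median centring, 159 in the deposited value table, 1589 without a filter on dim probes, 433 with probes well above background on all arrays, 566 with the replicate block and 1568 with array weights.

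The count of lists past the threshold, 9, was 5 with an estimated correlation, 4 with fry and 4 with the permutation of scores, and lay between 7 and 13 under the other alternatives. Leaving out 1 mouse gave 8 to 12. HIF targets passed in all 43 alternatives and glucocorticoid-responsive genes in all 44, with adjusted p from 3.21e-06 to 0.00285 and from 3.55e-18 to 0.00285. Most of these alternatives used camera at the preset correlation. Not counted among them, the scores of these lists permuted within slides gave adjusted p of 0.0107 and 0.013. Also not counted, HIF targets without members shared with other lists did not pass with an estimated correlation (adjusted p = 0.0637). Per mouse, 4 list scores passed, and 3 within slides, where that of immediate early genes was lost.

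Lists past the threshold that lost the call are given with their median log2 difference there. In the deposited value table they were antioxidant genes (-0.023), matrix genes (0.033) and red blood cell transcripts (0.227). Without Mt1 and Mt2, a choice made after seeing the data, 8 lists passed and antioxidant genes lost the call (0.073, adjusted p = 0.0712). With probes well above background on all arrays, immediate early genes (0.174, adjusted p = 0.21) lost it. Mesothelial markers lost it with Feature Extraction's ratio (0.203), with Cy5 alone (0.137) and without normoxia replicate 8, hypoxia replicate 1 or hypoxia replicate 9 (leaving out 1 mouse: 0.093 to 0.215). With an estimated correlation, with fry and with the permutation of scores, where medians stay as reported, matrix genes (0.120), smooth muscle (0.196), mesothelial (0.161) and red blood cell (0.361) lists lost it, and with fry and permutation also inflammatory genes (0.129).

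Lists not past the threshold that gained a call are given the same way. Camera kept the direction of the reported fit in each gained call, also where median centring gave a negative median. Macrophage markers gained it with median centring (-0.164), without a filter (0.076), with mean probes (0.073), with slide as a block (0.126), without slide 2 (0.126), with array weights (0.118) and without slide 1 (0.113). Glycolysis gained it with Feature Extraction's ratio (0.055), without a filter (0.058), with array weights (0.073), without slide 1 (0.047) and without the arrays with strong Cy3 (0.074). Angiogenic factors gained it with median centring (-0.169), without a filter (0.036), with array weights (0.075) and without slide 1 (0.077). Mast cell markers gained it with Cy5 alone (0.200), without a filter (0.105), with the replicate block (0.182) and without the arrays with strong Cy3 (0.096). Ribosomal proteins gained it with median centring (-0.278), array weights (0.055) and without the arrays with strong Cy3 (0.081). With median centring their median lay below that of all genes (-0.213), although camera's direction was up. Neuron and Schwann cell markers gained it without background correction (0.130), with median centring (-0.086) and in the deposited value table (0.076). Thermogenic genes gained it with probes well above background on all arrays (-0.191). With slide as a block and without slide 2, stem and progenitor markers (0.109 and 0.109) and testis germ cell transcripts (-0.767 and -0.767) gained it. Leaving out 1 mouse, some medians passed within ranges of 0.052 to 0.108 for macrophages, 0.031 to 0.091 for glycolysis, 0.022 to 0.071 for angiogenic factors, 0.117 to 0.191 for mast cells, -0.023 to 0.109 for ribosomal proteins, 0.066 to 0.115 for neurons and 0.004 to 0.098 for the cell cycle.

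Median centring moved the median of all genes to -0.21, so that with it even HIF targets had a median of -0.13, above that shift. Of 47 named genes with an unadjusted p under 0.05, 40 had the same sign in every alternative, as had 19 of the other 48. Median centring is among these alternatives, so that genes higher in hypoxia can change sign by its shift alone. The mice share only a number across groups: 2 of 10 same-numbered pairs had a correlation over 0.1 and 0 of 10 hypoxia mice correlated best with their own number. With the replicate block over replicates 1 to 10, 0 genes and 10 lists passed. The alternative with scan date as a block was not run, since the slides were scanned on 1 day at 1 time each.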

Other observations

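The comparison of red blood cell with white blood cell lists and the splits with an estimated correlation or balanced over slides were chosen after the results were seen, as were the use of the slide-blocked list test for red blood cells, the 2 transcript classes below, the lists without Mt1 and Mt2 and the check of the Pip5k1a and Pgk1 probes. The other tests were set before.

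Of the transcripts without a gene symbol, 2 classes were compared with the genes that have one. Of 1534 transcripts that the array names by a genomic coordinate, 62.0% lay below 0 with a median of -0.03, and of 209 named only as RIKEN clones, 76.1% did with a median of -0.06, against a median of 0.01 for genes with a symbol. Per mouse, the mean of the coordinate class less that of the symbol genes differed by -0.04 between groups (SD 0.03 in normoxia, n = 12, and 0.03 in hypoxia, n = 10; permutation p = 0.0217, adjusted over the 2 classes 0.0217). For the clone class it differed by -0.07 (SD 0.05 and 0.06, permutation p = 0.00411, adjusted 0.00822).

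Testis germ cell transcripts varied widely between mice. For Prm2 the SD was 1.86 in normoxia (n = 12) and 1.13 in hypoxia (n = 10), beside a group difference of -0.65 ± 0.59 (SE). The protamine gene Prm2, which packs DNA in sperm, ran from -3.35 in normoxia replicate 10 to 2.77 in normoxia replicate 1 on the log2 scale, and Smcp, a sperm mitochondrial protein, from -2.60 to 3.18 in the same mice. The score of the list was 2.75 in normoxia replicate 1 and 1.31 in hypoxia replicate 10.

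Glucocorticoid-responsive genes had the smallest p in camera at the preset correlation, and HIF targets in fry and in the permutation of scores. For the glucocorticoid score, a difference between slides could enter only through slide 2, since each of the other 5 slides carries 2 arrays of each group. By this layout the difference with slide as a block, 0.243 ± 0.055 (SE), had to stay near the 0.262 without it. A difference between slides as the whole cause is argued against by the layout and by a difference above 0 within each of the 5 slides (lowest 0.158). A shift of the Cy3 reference is argued against by a difference of -0.009 ± 0.010 in the Cy3 channel alone. With the red blood cell and smooth muscle scores as covariates the difference was 0.244 ± 0.072. This argues against a different share of blood or vessel-wall cells only as far as these scores follow those shares, which was not tested. Scores that follow them with error would remove only part of such an effect. What stays open includes the exposure itself, untested otherwise, and causes not tested here, such as shares of other cell types. No hormone value was analysed here. Of the 35 members, 8 are in other lists past the threshold, and the other 27 gave camera p = 3.75e-13.

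The HIF list shares 5 of its 39 members with other lists past the threshold, so that its shift could have come from those. Without them the other 34 members gave camera p = 0.000672 at the preset correlation (adjusted p = 0.00394), with a median of 0.06. At that correlation this argues against shared members as the whole cause. With an estimated correlation the adjusted p of camera was 0.0637, so that shared members as the whole cause are not excluded. The exposure itself and causes not tested here stay open.

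Red blood cell transcripts were higher in hypoxia by a score difference of 0.374, not past the threshold per mouse. A difference between slides could enter this only through slide 2, since each of the other 5 slides carries 2 arrays of each group. Whether the score difference within slides is more than chance cannot be decided, since it was imprecise and uneven. It was 0.367 ± 0.187 (SE) with slide as a block. Over the slides with both groups it ran from -0.046 to 1.176, with 0.444 the next highest. With slide as a block the list stayed past the threshold at the preset correlation (adjusted p = 4.93e-05). That p assumes a far lower correlation between members than the estimated 0.632. The scores permuted within slides gave an adjusted p of 0.258. Without the block the call was lost with an estimated correlation (adjusted p = 0.142) and with fry (adjusted p = 0.157). More blood of all cell types left in the tissue cannot be told apart, since the mean of the neutrophil, T and NK cell and B cell scores differed by 0.054 ± 0.055 and white cells resident in the fat would hide a small share. A change in the number of red cells in hypoxia was not tested otherwise.

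The arrays were also split into 12 and 10 at random, 100 splits in all with the real one. For genes past the threshold the splits decide nothing, since all 100 of 100 must give at least the real count of 0 (highest other 137). Genes at an unadjusted p under 0.05 were as many as the real 879 in 32 of 100 splits, with a highest other of 2627, so chance cannot be excluded for that count. A split with several times the real count points to structure among the samples apart from the groups. The 9 lists past the threshold with the preset correlation were matched in 14 of 100 splits, with a highest other of 14, so that chance cannot be excluded for that count. With an estimated correlation, 1 of 100 splits, the real one, gave 5 lists, and the highest other gave 1. No other split drawn matched that count, which makes chance unlikely but does not exclude it. The smallest share that 100 splits can give is 1 of 100, and this count was chosen after the results were seen. Splits with 2 arrays of each group on each of the 5 slides gave at least 879 genes in 25 of 100 (highest other 2662), at least 9 lists in 14 of 100 (highest other 16) and at least 5 lists with an estimated correlation in 1 of 100 (highest other 2), so that the same can be said with the slides balanced.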
